A study of Caenorhabditis elegans with 24 samples.

How the data were processed

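The series measured poly(A)+ RNA from mixed-stage embryos of Caenorhabditis elegans by RNA sequencing. Per the labels' protocols, worms were moved from plates seeded with OP50 bacteria into liquid culture with HB101 bacteria, kept there for 3 days at 20 degrees C, and their embryos were freed with hypochlorite. RNA was taken up in TRIzol, treated with DNase, and made into libraries with the TruSeq Stranded mRNA kit. Per the labels, 6 genotypes were sequenced with 4 libraries each, 24 libraries in all. They are the wildtype strain Bristol N2, the double mutant adr-1(uu49);adr-2(uu28), the single mutant rrf-3(uu56), the triple mutant of these 3 genes, and 2 quadruple mutants that add rde-1(uu51) or rde-4(uu53) to the triple mutant. Library numbers 1 to 4 were taken from the sample titles. The 4 libraries of a genotype are biological replicates per the series description, and a p-value measures the spread between these samples.

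The deposited count table holds whole-number read counts per gene for 17499 genes, with no normalization, per the file headers. The deposited FPKM table holds fragments scaled by gene length and library size for the same genes, per the file headers. The authors aligned the reads with Novoalign to the ce10 genome, per the submitters' processing notes. The version of the aligner, the counting program, the annotation release, the use of strand in counting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes, such as members of the pals, fbxa, math and histone families, may therefore be split between copies in ways that cannot be traced, and reads of overlapping or antisense genes cannot be told apart. Every gene in the table reached a count of at least 10 in some library. For the 16112 genes counted above 0 in every library, the FPKM values were the counts divided by 1 factor per library and 1 factor per gene, with a largest relative departure of 4.4e-08. The library size implied by the FPKM values was 0.9995 to 1.001 times the sum of the counts. Both tables thus hold the same measurement.

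Gene names came from the WBcel235 assembly with Ensembl release 115, which is not the build the authors used. It served only for symbols, biotypes and the order of genes along a chromosome, and no coordinates are given. Of the 17499 gene identifiers, 17187 matched a sequence name and 312 did not. Among those matched, 9119 carried a gene symbol, 15759 were protein coding and 688 were pseudogenes. The 312 others kept the identifier of the table.

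Total counts ran from 19200893 to 28938874 per library. Replicates of a genotype differed by far more than sampling noise, with a chi-square per degree of freedom of at least 17.2 in every pair, so no library was counted as a duplicate of another.

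Differential expression was tested on the deposited counts with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr over the 6 groups, which left 16367. Libraries were scaled by the trimmed mean of M values (TMM). One model with a mean per genotype was fitted to all 24 libraries with robust quasi-likelihood dispersions (18 residual degrees of freedom, median prior degrees of freedom 4.09). Each contrast was tested with the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method. A gene is called at an adjusted p below 0.05. All adjusted p-values of single genes printed here come from this test unless another is named. Levels are TMM-scaled CPM, given as mean ± SD of the 4 libraries of a genotype. Log2 fold changes are given ± standard error. There were 10 pairwise comparisons and the interaction of ADAR loss with rrf-3 loss.

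Gene groups came from 27 lists compiled from background knowledge. They cover 26G/ERI pathway factors, exogenous RNAi and mutator factors, secondary Argonautes, ERGO-1 class 26G siRNA targets, ADAR-edited transcripts, the intracellular pathogen response, the pals, F-box, MATH and BATH, C-type lectin, collagen, histone, major sperm protein and vitellogenin families, detoxification enzymes, heat shock and unfolded protein response genes, early zygotic genes, maternal germline transcripts, markers of muscle, intestine, pharynx, epidermis and neurons, heterochronic and vulval genes, sex determination and dosage compensation, nuclear RNAi and heterochromatin, and A-to-I editing and dsRNA-binding proteins. Lists were tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over the 27 lists of a comparison. Camera with an estimated correlation and fry were run beside it. With the estimated correlation 6 of 297 list tests passed, namely ERGO-1 targets in the rrf-3 mutant, the triple mutant and both quadruple mutants against N2 and in the triple against the double mutant, and detoxification enzymes in the triple against the rrf-3 mutant. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

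The genotype contrasts, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 5 mutated genes in every group. For adr, rrf3 and the triple mutant against N2, and for each quadruple mutant against the triple mutant, it takes up to 8 rising and 8 falling called genes whose groups do not overlap and whose higher group has a mean of at least 5 CPM, by size of change. For other comparisons it takes 3 and 3. It adds the 3 called members with the smallest p of each list that passed, and in those 5 comparisons up to 4 members of the ERGO-1 target, ADAR-edited and pathogen response lists.

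The share of the triple mutant change that a quadruple mutant returned was computed with genes called between 2 libraries of N2 and 2 of the triple mutant, over the 6 ways to choose them. The fit for these calls also held all adr and rrf3 libraries. The change was measured in the other 2 libraries of N2 and of the triple mutant and in all 4 libraries of the quadruple mutant. Comparisons that share control libraries were set beside 40 simulated draws of unchanged groups and beside controls divided into 2 pairs in 6 ways. Calls shared by comparisons without common libraries were set beside 34 divisions of N2, adr, rrf3 and triple mutant libraries with group means removed and same-numbered libraries kept together, a test added after the results were seen.

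The alternatives were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no filter, a filter of at least 1 CPM in at least 4 libraries, a fit to the 2 groups compared, the library number as a block, an adjusted p below 0.01, at least a 2-fold change, limma on log2 FPKM with a pseudocount of 0.1, and leaving out each library in turn. After the data were seen, 6 were added, namely embryo stage markers as 3 covariates in the gene test and in camera, list tests without N2 replicate 2, a pseudocount of 1 for FPKM, divided controls for the calls that the triple and each quadruple mutant share against N2, and the library number as a block for the members of a list called. The stage covariates of a library are its mean log2 CPM over the late tissue markers (muscle, intestine, pharynx, epidermis, neurons), over the maternal list and over the early zygotic list.

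Library numbers were checked as a pairing by correlating the deviations of same-numbered libraries from their group means. Every correlation was over 0.1, the bound used for a pairing, for adr vs N2 (0.42 to 0.75, with 5 of 8 libraries closest to their own number), the triple mutant vs rrf3 (0.11 to 0.53, 4 of 8), the rde-1 quadruple mutant vs the triple mutant (0.31 to 0.73, 8 of 8), the rde-4 quadruple mutant vs N2 (0.42 to 0.73, 7 of 8) and between the quadruple mutants (0.34 to 0.79, 6 of 8). The rde-4 quadruple mutant vs the triple mutant fell short of the bound (0.04 to 0.74) with 6 of 8, so the line is not sharp. The labels do not say what a number stands for. In these 5 comparisons the value with the number as a block is given for the reported counts, list tests and list members that it changes.

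The scripts were tested on simulated counts for adr vs N2 with 16149 genes. The test recovered 5.97% of 67 genes changed 1.5-fold, 50.7% of 67 changed 2-fold and 97% of 66 changed 4-fold, and 4.67% of 107 calls were false. Camera gave an unadjusted p below 0.05 for 6 of 99 random lists. With a simulated return of 60%, the share returned came out at 59.2% for rising and 57.6% for falling genes, and with a simulated return of 0% at -2.75% and 1.16%. Apart from the changes put in, each gene was drawn independently around 1 mean for all libraries. Embryo age, deviations shared by library number and correlation between genes were not simulated, so these rates may not hold for the data. Figures were drawn with matplotlib 3.10.9.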

Results

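RNA was sequenced from mixed-stage embryos of 6 strains of C. elegans, with 4 libraries per strain. ADR-1 and ADR-2 are the worm's adenosine deaminases acting on RNA (ADARs), which act on double-stranded RNA, and ADR-2 is the active enzyme. RRF-3 is an RNA-dependent RNA polymerase that makes the 26G class of small RNAs, which the Argonaute ERGO-1 binds in embryos. RDE-1 is the Argonaute of exogenous RNAi, and RDE-4 is the double-stranded RNA binding partner of Dicer in that pathway. The strains allow loss of the ADARs to be compared with and without the 26G pathway, and then with and without factors of exogenous RNAi. The list of 26G/ERI pathway factors also holds rde-4, so the rde-4 strain does not bear on exogenous RNAi alone. Total counts per library were 21418271 to 28938874 in N2, 20922644 to 25083555 in the adr double mutant, 21056409 to 25216455 in the rrf-3 mutant, 20951759 to 21674226 in the triple mutant, 19200893 to 26124829 in the rde-1 quadruple mutant and 21245135 to 23765053 in the rde-4 quadruple mutant. Between 204 and 728 genes of the table had no read in the N2 libraries and between 244 and 416 in the adr libraries. In libraries of the strains that lack rrf-3 the number ran from 12 to 186.

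The mutated genes were examined first. In the adr double mutant adr-1 (H15N14.1) was at 30.6 ± 2.85 CPM against 244 ± 86.9 CPM in N2 (log2 fold change -3 ± 0.20, adjusted p = 4.1e-09). It was at 195 ± 35.8 CPM in the rrf-3 mutant and between 27.1 ± 1.98 and 29.3 ± 4.66 CPM in the other strains that carry the adr mutations. Libraries of the 4 strains with the adr-2 mutation held 0 to 6 reads of adr-2 (T20H4.4), against 172 ± 61.1 CPM in N2 and 123 ± 12.3 CPM in the rrf-3 mutant. The transcript of rde-1 (K08H10.7) was at 7.6 ± 1.75 CPM in the rde-1 quadruple mutant and between 76.4 ± 4.16 and 88.1 ± 16.1 CPM elsewhere. That of rde-4 (T20G5.11) was at 6.69 ± 0.682 CPM in the rde-4 quadruple mutant and between 61.1 ± 8.84 and 94.6 ± 36.9 CPM elsewhere. The transcript of rrf-3 (F10B5.7) differed less. It was at 86.5 ± 38.4 CPM in N2, 75.1 ± 15.5 CPM in the adr double mutant and 50.5 ± 9.53 CPM in the rrf-3 mutant (log2 fold change against N2 -0.77 ± 0.22, adjusted p = 0.063). It stood at 46.3 ± 4.64 CPM in the triple mutant, 45.6 ± 7.04 CPM in the rde-1 and 51.1 ± 8.82 CPM in the rde-4 quadruple mutant. The call of rrf-3 in the triple mutant against N2 (log2 fold change -0.90 ± 0.22, adjusted p = 0.0098) ended without N2 replicate 2 (adjusted p = 0.055). The level of this transcript is therefore a weak check of the rrf-3 labels, while the other 4 genes go with theirs in every library.

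**Figure D1:**
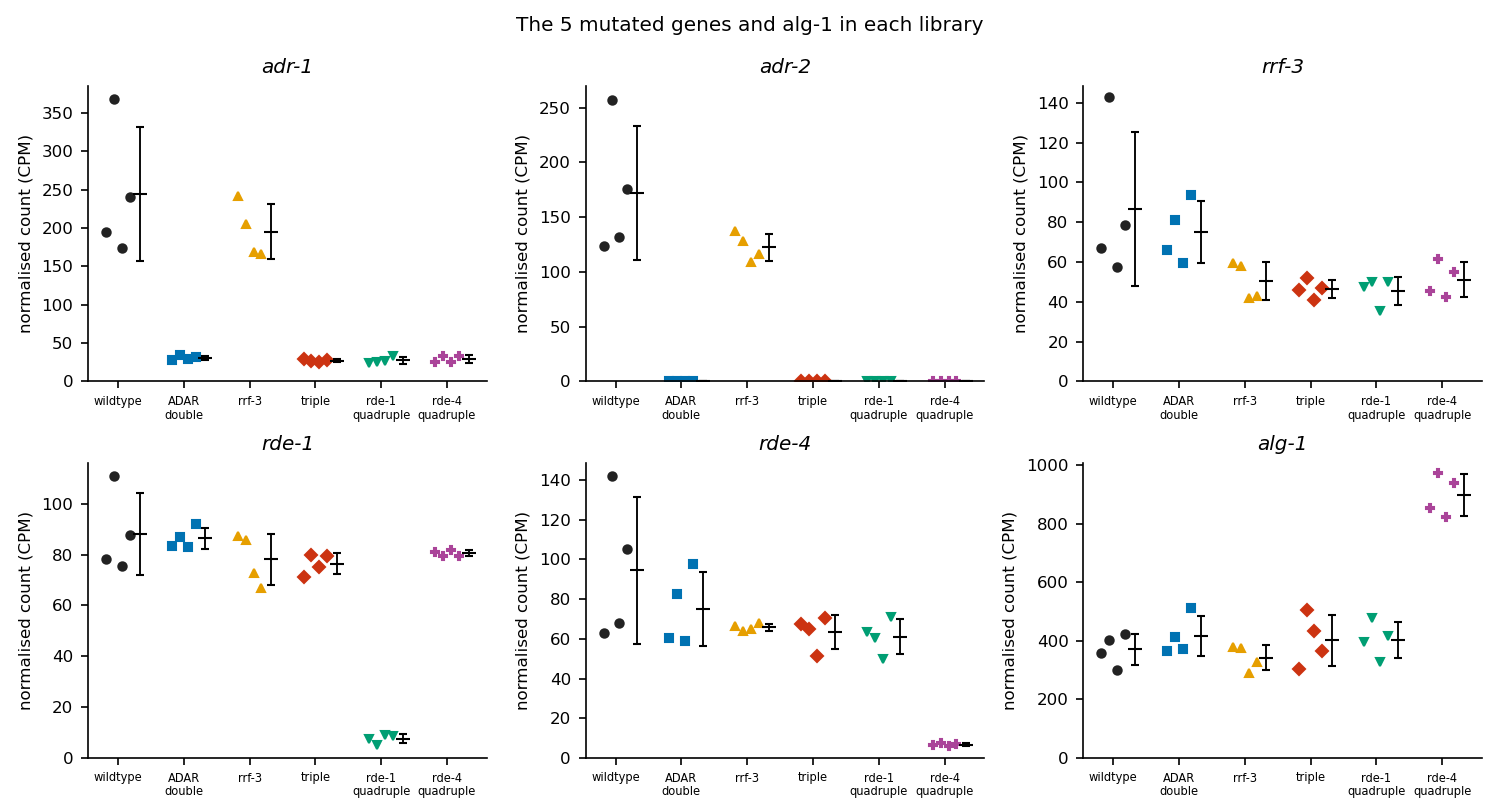
TMM-scaled CPM of alg-1 and the 5 mutated genes in each strain. Points are single libraries and the bars give mean ± SD of 4 libraries. Levels of rde-1, rde-4 and both adr genes are low in each strain that carries the mutation, rrf-3 overlaps between strains, and alg-1 lies between 821 and 974 CPM in the rde-4 quadruple mutant and between 290 and 512 CPM in the 20 other libraries.

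Embryos differ in age between libraries, and maternal and early zygotic means moved with the strains. The mean log2 CPM of 34 maternal germline transcripts was 5.932 ± 0.623 in N2, 5.733 ± 0.295 in the adr double mutant, 5.53 ± 0.185 in the rrf-3 mutant, 5.095 ± 0.288 in the triple mutant, 5.264 ± 0.295 in the rde-1 quadruple mutant and 5.497 ± 0.328 in the rde-4 quadruple mutant. The 34 early zygotic genes went from 4.441 ± 0.594 in N2 to 3.713 ± 0.338 in the triple mutant. N2 replicate 2 stood apart, with a maternal mean of 6.78 against 5.36, 5.6 and 5.99 in the other N2 libraries, a late tissue mean of 4.64 and a TMM factor of 0.775. The first 2 principal components held 56.4% and 17.1% of the variance.

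**Figure D2:**
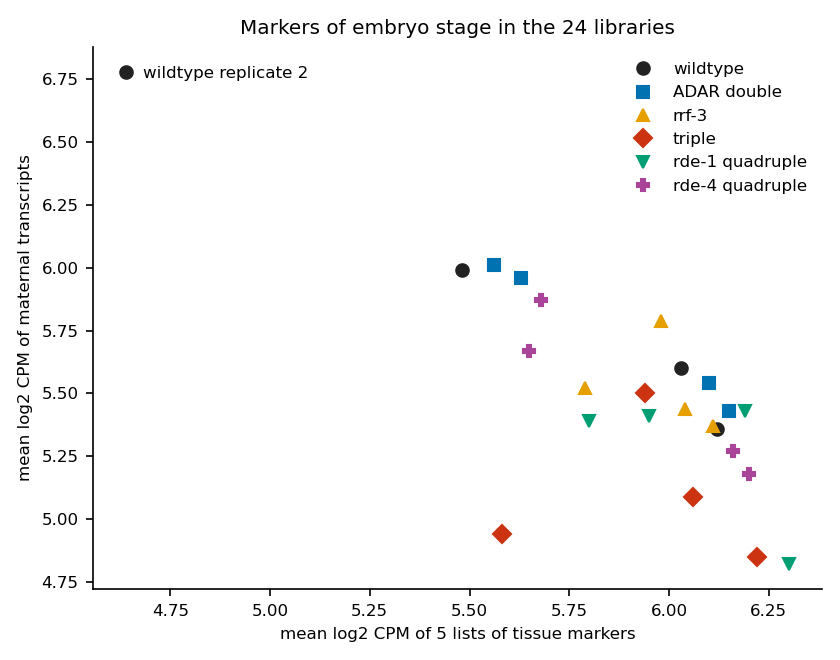
Mean log2 CPM of late tissue markers (muscle, intestine, pharynx, epidermis, neurons; horizontal axis) and of maternal germline transcripts (vertical axis) in the 24 libraries, coloured by strain. N2 replicate 2 lies at 4.64 and 6.78, and the other libraries have maternal means between 4.82 and 6.01.

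Loss of both ADARs alone was assessed by the adr double mutant against N2. Besides adr-1 and adr-2, few transcripts changed. The transcript of alh-7 (F45H10.1), an aldehyde dehydrogenase gene on the list of ADAR-edited transcripts, fell from 31.1 ± 5.07 to 11.5 ± 1.66 CPM (log2 fold change -1.43 ± 0.23, adjusted p = 0.0038). Levels of nstp-1 (C53B4.6), a predicted nucleotide sugar transporter gene, fell from 15 ± 1.54 to 7.17 ± 0.318 CPM (-1.06 ± 0.14, adjusted p = 0.00044), and Y51F10.4 fell from 58.9 ± 13.7 to 31.2 ± 1.23 CPM (-0.92 ± 0.13, adjusted p = 0.00045). The pseudogene W06A11.4 rose from 2.73 ± 0.453 to 9.11 ± 1.49 CPM (1.74 ± 0.21, adjusted p = 1e-04). The F-box gene fbxa-192 (F57G4.8) rose from 3.98 ± 1.22 to 13.6 ± 3.44 CPM (1.77 ± 0.29, adjusted p = 0.0047), a call that ended without N2 replicate 1 or adr replicate 4 (adjusted p = 0.057 in each case). In all, 17 of 16367 genes were called, 6 higher and 11 lower, and 25 with library number as a block. With only the 8 libraries of these strains in the fit 2 genes were called, adr-1 and adr-2, and alh-7, nstp-1, Y51F10.4, W06A11.4 and fbxa-192 were not (adjusted p = 0.086, 0.45, 0.49, 0.12 and 0.36).

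Among gene groups in the adr double mutant, 1 of 13 ADAR-edited transcripts was lower, alh-7, and the count was also 1 when adjusted over the list alone. The list had a median log2 fold change of -0.21 (camera adjusted p = 0.00868, and adjusted p = 0.556 with an estimated correlation or 0.123 without N2 replicate 2). Of the 29 genes of the intracellular pathogen response, a programme induced by microsporidia and virus infection, 0 were called by edgeR and 1 was higher when adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.169). With library number as a block 1 member was higher, C53A5.9 (1.91 ± 0.34, adjusted p = 0.016), which DESeq2 called as well (1.82, adjusted p = 0.039). The pals family, whose members are prominent in that programme, had a median of 0.11 and a mean of -0.06 over 34 genes, with 0 called (camera adjusted p = 0.092, or 0.0337 with library number as a block, and adjusted p = 0.859 with an estimated correlation). Targets of ERGO-1 class 26G small RNAs had 0 of 24 called and a median of -0.07 (camera adjusted p = 0.703). Intestine markers had a median of 0.18 (camera adjusted p = 0.0653, or 0.048 with the block, and 0.662 with an estimated correlation). Maternal transcripts had a median of -0.31 (camera adjusted p = 0.0011, and adjusted p = 0.646 with an estimated correlation), and without N2 replicate 2 the test turned to higher (adjusted p = 0.0278). Early zygotic genes had a median of -0.40 (camera adjusted p = 3.9e-05, and adjusted p = 0.646 with an estimated correlation), with an adjusted p of 0.764 without that library.

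Loss of the 26G pathway alone was assessed by the rrf-3 mutant against N2. The ERGO-1 targets rose together. F55C9.3 went from 6.2 ± 2.63 to 214 ± 26.2 CPM (log2 fold change 5.11 ± 0.28, adjusted p = 1.8e-11), F55C9.5 from 6.8 ± 1.93 to 167 ± 20.2 CPM (4.62 ± 0.22, adjusted p = 3.4e-12), K02E2.6 from 14.3 ± 3.26 to 101 ± 10.3 CPM (2.82 ± 0.18, adjusted p = 3.1e-10) and the pseudogenes F39E9.7 from 14 ± 6.84 to 289 ± 32.1 CPM (4.36 ± 0.29, adjusted p = 4.4e-10) and W05H12.2 from 14.9 ± 2.6 to 90.2 ± 7.71 CPM (2.60 ± 0.14, adjusted p = 1.8e-11). Of 24 targets tested, 20 were higher and 0 lower, or 21 higher when adjusted over the list alone, with a median of 2.73 (camera adjusted p = 4.35e-48, and adjusted p = 2.38e-06 with an estimated correlation). Among the largest changes outside that list were the non-coding RNA F40D4.16, from 0.732 ± 0.354 to 24.8 ± 3.35 CPM (5.04 ± 0.32, adjusted p = 2.7e-10), and the infection response gene irg-5 (F35E12.5), from 0.404 ± 0.492 to 9.16 ± 4.71 CPM (4.44 ± 0.94, adjusted p = 0.0089).

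Genes of the intracellular pathogen response rose in the rrf-3 mutant as well. In this strain pals-28 (B0284.4) went from 0.139 ± 0.14 to 3.91 ± 2.2 CPM (log2 fold change 4.74 ± 0.76, adjusted p = 0.00056), pals-6 (C17H1.7) from 0.615 ± 0.482 to 8.01 ± 4.31 CPM (3.68 ± 0.67, adjusted p = 0.0023) and the F-box gene fbxa-75 (Y119D3A.1) from 0.236 ± 0.22 to 3.23 ± 1.77 CPM (3.73 ± 0.72, adjusted p = 0.004). Of the list, 18 of 29 members were higher and 0 lower, or 25 higher when adjusted over the list alone, with a median of 2.38 (camera adjusted p = 1.2e-21, and adjusted p = 0.336 with an estimated correlation). Without N2 replicate 2, 9 members were higher. In the pals family 12 of 34 were higher, or 20 when adjusted over the list alone, with a median of 2.16 (camera adjusted p = 1.4e-16, and adjusted p = 0.426 with an estimated correlation). The heat shock gene hsp-70 (C12C8.1) rose from 3.91 ± 1.92 to 34.7 ± 20.2 CPM (3.16 ± 0.52, adjusted p = 0.00087). Heat shock and unfolded protein response genes had 2 of 12 members higher, or 4 when adjusted over the list alone (median 0.57, camera adjusted p = 0.00914, and adjusted p = 0.608 with an estimated correlation). C-type lectins had 8 of 108 higher, or 10 when adjusted over the list alone (median 0.18, camera adjusted p = 0.00914, and adjusted p = 0.61 with an estimated correlation), among them clec-1 (F25B4.9) at 14.7 ± 5.43 against 4.11 ± 2.62 CPM (1.83 ± 0.38, adjusted p = 0.0074), a call that ended with only the 8 libraries of these strains in the fit (adjusted p = 0.15). Without N2 replicate 2 the lectin list had an adjusted p of 0.524. Markers of age moved in the same comparison. Early zygotic genes had a median of -0.68 and 0 called (camera adjusted p = 2.58e-07, and adjusted p = 0.608 with an estimated correlation), and maternal transcripts a median of -0.63 and 0 called (camera adjusted p = 2.88e-05, and adjusted p = 0.61 with an estimated correlation, or 0.251 without N2 replicate 2).

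In total 485 genes were called in the rrf-3 mutant, 476 higher and 9 lower. Among those lower were sax-2 (F21H11.2), a furry family gene, at 204 ± 26.1 against 365 ± 152 CPM (log2 fold change -0.83 ± 0.23, adjusted p = 0.048), and nduv-3 (Y69A2AR.3), a gene of mitochondrial complex I, at 60.2 ± 3.66 against 82.1 ± 8.53 CPM (-0.45 ± 0.11, adjusted p = 0.032). Each of these 2 calls ended in 6 of the 8 omissions of a library, with adjusted p between 0.066 and 0.24 for sax-2 (without N2 replicates 2 or 4 or any rrf3 library) and between 0.066 and 0.15 for nduv-3 (without N2 replicates 3 or 4 or any rrf3 library), and with only the 8 libraries of these strains in the fit (adjusted p = 0.34 and 0.36), where 130 genes were called in all. The count itself was 1084 without N2 replicate 1, 251 without N2 replicate 2, 232 without N2 replicate 3, 258 without N2 replicate 4, 793 without rrf3 replicate 2 and 207 without rrf3 replicate 3. F55C9.3, F55C9.5, F40D4.16, pals-28 and hsp-70 stayed called in each of the 8 omissions.

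Joint loss of the ADARs and the 26G pathway was assessed by the triple mutant against N2, which gave the largest number of calls of the 10 comparisons. ERGO-1 targets were higher to about the extent seen without rrf-3 alone, with F55C9.3 at 224 ± 24.2 CPM (log2 fold change 5.18 ± 0.28, adjusted p = 1.7e-11) and 21 of 24 members higher, 21 also when adjusted over the list alone (median 2.85, camera adjusted p = 1.04e-30, and adjusted p = 5.7e-05 with an estimated correlation). Intracellular pathogen response genes were higher, with pals-28 at 9.6 ± 3.96 CPM (6.03 ± 0.77, adjusted p = 2.2e-05), pals-6 at 15 ± 6.75 CPM (4.59 ± 0.69, adjusted p = 0.00016) and C53A5.9 at 21.4 ± 7.7 against 1.45 ± 0.841 CPM (3.86 ± 0.50, adjusted p = 2.5e-05). Of the list 26 of 29 were higher, or 28 higher and 1 lower when adjusted over the list alone (median 3.71, camera adjusted p = 7.82e-21, and adjusted p = 0.265 with an estimated correlation). The pals family had 26 of 34 higher, or 27 when adjusted over the list alone (median 2.95, camera adjusted p = 5.02e-18, and adjusted p = 0.265 with an estimated correlation).

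Some detoxification and stress genes rose in the triple mutant too. The glutathione S-transferase gene gst-24 (F37B1.1) went from 1.55 ± 0.911 to 39 ± 15.1 CPM (log2 fold change 4.63 ± 0.62, adjusted p = 4.2e-05) and the cytochrome P450 gene cyp-13A10 (ZK1320.4) from 13.2 ± 1.72 to 28 ± 5.89 CPM (1.09 ± 0.16, adjusted p = 9.6e-05). Detoxification enzymes had 38 of 155 members higher and 3 lower, or 38 and 4 when adjusted over the list alone (median 0.37, camera adjusted p = 1.78e-05, and adjusted p = 0.265 with an estimated correlation). hsp-70 was at 47.4 ± 10.8 CPM (3.61 ± 0.53, adjusted p = 0.00013), and heat shock and unfolded protein response genes had 4 of 12 higher, or 6 when adjusted over the list alone (median 0.68, camera adjusted p = 0.0283, and adjusted p = 0.565 with an estimated correlation). MATH and BATH domain genes had 18 of 61 higher and 6 lower, or 18 and 7 when adjusted over the list alone (median 0.33, camera adjusted p = 0.0305, and adjusted p = 0.565 with an estimated correlation). C-type lectins had 19 of 108 higher and 6 lower, the same counts when adjusted over the list alone (median 0.22, camera adjusted p = 0.0139, and adjusted p = 0.658 with an estimated correlation). Collagens had 22 of 118 higher and 0 lower, or 21 when adjusted over the list alone (median 0.18, camera adjusted p = 0.000339, and adjusted p = 0.658 with an estimated correlation). Intestine markers had 4 of 20 higher, also 4 when adjusted over the list alone (median 0.27, camera adjusted p = 0.0345, and adjusted p = 0.658 with an estimated correlation). Without N2 replicate 2 the lectins and the intestine markers had an adjusted p of 0.317 and the collagens of 0.256. F-box genes went both ways, with 59 of 270 higher and 103 lower, or 74 and 113 when adjusted over the list alone. Their median was -0.32, their mean 0.17 and the test leaned lower (camera adjusted p = 0.191).

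Transcripts that the mother supplies to the embryo fell in the triple mutant. The Notch receptor gene glp-1 (F02A9.6) went from 215 ± 122 to 84.4 ± 24.6 CPM (log2 fold change -1.35 ± 0.30, adjusted p = 0.0057), and oma-2 (ZC513.6), a gene of oocyte maturation, from 67.7 ± 38.7 to 23.3 ± 9.7 CPM (-1.54 ± 0.34, adjusted p = 0.0052). Maternal germline transcripts had 24 of 34 lower and 0 higher, 24 also when adjusted over the list alone (median -1.08, camera adjusted p = 5.84e-09, and adjusted p = 0.565 with an estimated correlation). Early zygotic genes had 17 of 34 lower, or 24 when adjusted over the list alone (median -0.93, camera adjusted p = 4.38e-07, and adjusted p = 0.565 with an estimated correlation). Lower with them were 26G/ERI pathway factors, 6 of 10, with rrf-3 itself among them, or 9 when adjusted over the list alone (median -0.76, camera adjusted p = 0.00065, and adjusted p = 0.565 with an estimated correlation), and exogenous RNAi and mutator factors, 11 of 21 or 15 when adjusted over the list alone (median -0.57, camera adjusted p = 0.000239, and adjusted p = 0.565 with an estimated correlation). In the latter list mut-2 (K04F10.6), a nucleotidyltransferase gene needed for transposon silencing, went from 46.7 ± 18.4 to 22.1 ± 5.27 CPM (-1.08 ± 0.26, adjusted p = 0.0084). Nuclear RNAi and heterochromatin genes had 6 of 19 lower, or 13 when adjusted over the list alone (median -0.55, camera adjusted p = 0.000419, and adjusted p = 0.657 with an estimated correlation, or 0.0874 without N2 replicate 2). A-to-I editing and dsRNA-binding proteins had 5 of 15 lower, or 14 when adjusted over the list alone, and the 5 include adr-1 and adr-2 themselves (median -0.57, camera adjusted p = 2.55e-07, and adjusted p = 0.5 with an estimated correlation). Histones had 6 of 32 lower, or 5 when adjusted over the list alone (median -0.43, camera adjusted p = 0.00464, and adjusted p = 0.658 with an estimated correlation). Sex determination and dosage compensation genes had 1 of 20 higher and 4 lower, or 3 and 12 when adjusted over the list alone (median -0.49, camera adjusted p = 0.014, and adjusted p = 0.658 with an estimated correlation). Without N2 replicate 2 each of the last 2 lists had an adjusted p of 0.317.

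The other lists did not pass in the triple mutant. Secondary Argonautes had 2 of 13 higher and 2 lower, or 3 and 3 when adjusted over the list alone, with a median of -0.05 and a mean of 0.13 (camera adjusted p = 0.807). ADAR-edited transcripts had 2 of 13 higher and 3 lower, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.353). Among the 3 lower, alh-7 was at 12.6 ± 3.3 CPM (log2 fold change -1.30 ± 0.23, adjusted p = 0.00076). No member of the major sperm proteins (4 tested, median 0.26, camera adjusted p = 0.816), the vitellogenins (3 tested, median 0.56, camera adjusted p = 0.509) or the muscle markers (27 tested, median 0.23, camera adjusted p = 0.102) was called by edgeR. Pharynx markers had 1 of 18 higher (median 0.14, camera adjusted p = 0.0824), epidermis markers 1 of 24 higher and 1 lower (median -0.21, camera adjusted p = 0.0824), neuron markers 1 of 32 lower or 0 when adjusted over the list alone (median 0.22, with the test leaning higher, camera adjusted p = 0.0743) and heterochronic and vulval genes 3 of 31 lower (median -0.06, camera adjusted p = 0.304).

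In all 3930 genes were called in the triple mutant, 1817 higher and 2113 lower, and 2029 of them by at least 2-fold, 1494 higher and 535 lower. With limma on log2 FPKM the split was 2616 higher and 895 lower. The count was 1501 without N2 replicate 2, 1618 without N2 replicate 4 and 1169 without adr_rrf3 replicate 3. With only the 8 libraries of these strains in the fit 688 genes were called, and not glp-1, oma-2, mut-2 or rrf-3 (adjusted p = 0.076, 0.069, 0.081 and 0.11). With stage markers as covariates 369 genes were called, 318 of them shared. The lower call of mut-2 then ended (adjusted p = 0.25), as did those of glp-1 and oma-2 (0.52 and 0.32), which belong to a list that makes up 1 of the covariates and so are adjusted for themselves in part. The calls of F55C9.3, pals-28, pals-6, C53A5.9, gst-24, cyp-13A10, hsp-70 and alh-7 held.

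Loss of the ADARs where rrf-3 is already missing was assessed by the triple mutant against the rrf-3 mutant. adr-1 (log2 fold change -2.85 ± 0.20, adjusted p = 1e-08) and adr-2 fell. The transcript of alh-7 was lower again, at 12.6 ± 3.3 against 29.7 ± 6.17 CPM (-1.23 ± 0.23, adjusted p = 0.038), and so was the pseudogene Y48G1BL.3, at 4.43 ± 1.53 against 12.1 ± 0.86 CPM (-1.45 ± 0.25, adjusted p = 0.019). Only 8 genes were called, 0 higher and 8 lower, and 16 with library number as a block (2 higher and 14 lower). All 8 were also among the 11 lower in the adr double mutant, where 0.00538 would be shared by independent lists. The call of alh-7 ended in 7 of the 8 omissions of a library, all but adr_rrf3 replicate 1, with adjusted p between 0.057 and 0.32, and that of Y48G1BL.3 in all but adr_rrf3 replicate 4, with adjusted p between 0.066 and 0.16. Both ended with only the 8 libraries of these strains in the fit (adjusted p = 0.14 and 0.069). The count was 5 without rrf3 replicate 1 and 5 without rrf3 replicate 2.

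Some gene groups leaned further in the triple mutant than in the rrf-3 mutant. The intracellular pathogen response list had 0 of 29 called, also 0 when adjusted over the list alone, and a median of 1 (camera adjusted p = 7.78e-15, and adjusted p = 0.435 with an estimated correlation). The pals family had 0 of 34 called and a median of 0.84 (camera adjusted p = 5.56e-14, and adjusted p = 0.435 with an estimated correlation). Detoxification enzymes had 0 of 155 called and a median of 0.25 (camera adjusted p = 1.3e-12, and adjusted p = 0.0351 with an estimated correlation). Maternal transcripts had a median of -0.44 (camera adjusted p = 1.27e-11, and adjusted p = 0.518 with an estimated correlation). ERGO-1 targets had 0 of 24 called and a median of 0.11 (camera adjusted p = 0.0949). The block changed the side of the threshold for ADAR-edited transcripts (1 of 13 lower, alh-7, median -0.01, mean -0.19, camera adjusted p = 0.0376 and 0.0584 with the block), MATH and BATH genes (0.0441 and 0.0584), 26G/ERI factors (0.0536 and 0.0265) and sex determination genes (0.0845 and 0.0367), and with an estimated correlation these 4 had an adjusted p of 0.435, 0.536, 0.852 and 0.852.

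Loss of rrf-3 where the ADARs are already missing was assessed by the triple mutant against the adr double mutant. ERGO-1 targets and pathogen response genes rose here too. F55C9.3 was at 224 ± 24.2 against 5.17 ± 1.08 CPM (log2 fold change 5.44 ± 0.28, adjusted p = 1e-11) and pals-28 at 9.6 ± 3.96 against 0.246 ± 0.123 CPM (5.30 ± 0.72, adjusted p = 6.5e-05). Outside these 2 lists F19B10.13 was at 37.4 ± 14.1 against 0.854 ± 0.236 CPM (5.45 ± 0.72, adjusted p = 4.1e-05) and the detoxification gene gst-24 at 39 ± 15.1 against 1.67 ± 0.168 CPM (4.54 ± 0.61, adjusted p = 5.9e-05). ERGO-1 targets had 21 of 24 higher, also when adjusted over the list alone (median 2.77, camera adjusted p = 4.83e-44, and adjusted p = 4.56e-06 with an estimated correlation). Pathogen response genes had 26 of 29 higher, or 27 when adjusted over the list alone (median 3.62, camera adjusted p = 1.88e-27, and adjusted p = 0.173 with an estimated correlation). Detoxification enzymes had 23 of 155 higher and 1 lower, or 26 and 1 when adjusted over the list alone (median 0.21, camera adjusted p = 0.000116, and adjusted p = 0.286 with an estimated correlation). Maternal transcripts had 1 of 34 lower, or 22 when adjusted over the list alone (median -0.73, camera adjusted p = 2.69e-07, and adjusted p = 0.814 with an estimated correlation). The member called was oma-2, at 23.3 ± 9.7 against 53.1 ± 14.8 CPM (-1.19 ± 0.34, adjusted p = 0.031), a call that ended without adr replicates 2 or 4 or adr_rrf3 replicates 1, 2 or 3 (adjusted p between 0.073 and 0.12). In all 1397 genes were called, 1268 higher and 129 lower, and 279 with stage markers as covariates, 265 higher and 14 lower. The count was 911 without adr replicate 2, 906 without adr_rrf3 replicate 1 and 708 without adr_rrf3 replicate 3.

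The 2 effects of rrf-3 loss, measured in libraries that do not overlap, were compared by their calls. Of the 476 genes higher in the rrf-3 mutant against N2, 443 were also among the 1268 higher in the triple against the double mutant, where 36.9 would be shared by independent lists. Of the 9 lower, 4 were among the 129 lower (0.0709 for independent lists). Library numbers pair N2 with adr and the triple with the rrf-3 mutant, so such deviations can be shared. With the group means removed and same-numbered libraries kept together, 34 other divisions shared at most 0 calls in either direction. The correlation of fold changes across genes was 0.898, where these divisions gave a mean of 0.474 and a range of -0.174 to 0.851. Whether the effect of ADAR loss depends on rrf-3 was tested as an interaction. Here edgeR called 0 of 16367 genes, 137 had an unadjusted p below 0.05, and DESeq2 called 1, lower.

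**Figure D3:**
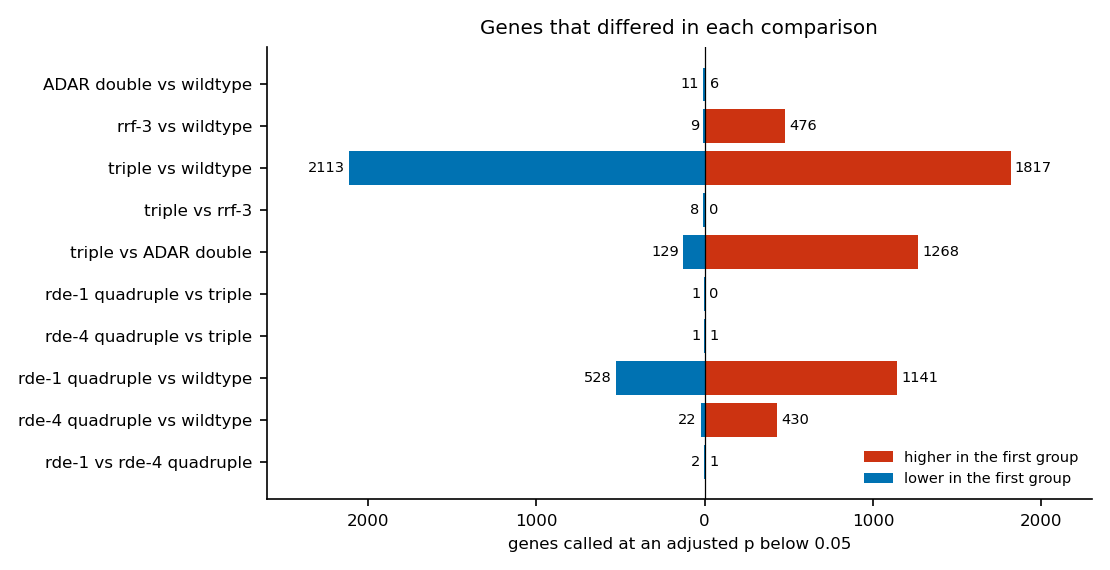
Number of genes called higher and lower (adjusted p below 0.05, edgeR quasi-likelihood test) in each of the 10 pairwise comparisons. The counts run from 1 for the rde-1 quadruple mutant against the triple mutant to 3930 for the triple mutant against N2.

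Loss of rde-1 from the triple mutant was assessed by the rde-1 quadruple mutant. The rde-1 transcript itself fell from 76.4 ± 4.16 to 7.6 ± 1.75 CPM (log2 fold change -3.33 ± 0.16, adjusted p = 5.4e-12), and it was the only gene called by edgeR. Here 121 genes had an unadjusted p below 0.05, DESeq2 called 2, and with library number as a block 3 were called. Without adr_rrf3 replicate 3 there were 2. The further genes, chosen after their values were seen, were Y48G1BL.4, higher with DESeq2 (1.63, adjusted p = 0.00095), with the block (1.67 ± 0.28, adjusted p = 0.043) and without that library (1.99 ± 0.33, adjusted p = 0.049), and Y48G1BL.3, higher with the block (1.10 ± 0.18, adjusted p = 0.035). Genes of the pathogen response had values below those of the triple mutant without passing the test, with pals-28 at 5.56 ± 3.21 against 9.6 ± 3.96 CPM (-0.79 ± 0.56, adjusted p = 1). That list had 0 of 29 called, also 0 when adjusted over the list alone, and a median of -0.44 (camera adjusted p = 1.77e-09, and adjusted p = 0.993 with an estimated correlation). Detoxification enzymes had a median of -0.09 (camera adjusted p = 3.01e-07, and adjusted p = 0.292 with an estimated correlation), and maternal transcripts a median of 0.17 (camera adjusted p = 0.0168, and adjusted p = 0.993 with an estimated correlation). Histones and muscle markers passed without the block (camera adjusted p = 0.0256 and 0.0317) and not with it (0.0724 and 0.0883), and both had an adjusted p of 0.993 with an estimated correlation. ERGO-1 targets had a median of -0.03 (camera adjusted p = 0.494).

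Loss of rde-4 from the triple mutant was assessed by the rde-4 quadruple mutant. The rde-4 transcript fell from 63.5 ± 8.55 to 6.69 ± 0.682 CPM (log2 fold change -3.25 ± 0.23, adjusted p = 2e-08). The microRNA Argonaute gene alg-1 (F48F7.1) rose from 402 ± 86.3 to 897 ± 71.7 CPM (1.16 ± 0.16, adjusted p = 0.003). No other gene was called by edgeR, 350 had an unadjusted p below 0.05, and without adr_rrf3 replicate 4 or adr_rrf3_rde4 replicate 2 only rde-4 passed (adjusted p of alg-1 0.096 and 0.056), as with the 2 groups fitted alone (0.38). DESeq2 also called Y48G1BL.4 (1.49, adjusted p = 0.011) and the fit with library number as a block Y48G1BL.3 (1.13 ± 0.18, adjusted p = 0.016), which were both chosen after their values were seen. Library numbers fell short of the bound for a pairing in this comparison (correlations 0.04 to 0.74). Of the 8 libraries, 6 were closest to their own number. Pathogen response genes had 0 of 29 called, also 0 when adjusted over the list alone, and a median of -1.14 (camera adjusted p = 1.87e-23, and adjusted p = 0.24 with an estimated correlation). Among them C53A5.9 was at 7.54 ± 4.02 against 21.4 ± 7.7 CPM (-1.50 ± 0.44, adjusted p = 1). Detoxification enzymes had a median of -0.21 (camera adjusted p = 6.59e-08, and adjusted p = 0.231 with an estimated correlation). Maternal transcripts had a median of 0.48 (camera adjusted p = 9.81e-10, and adjusted p = 0.783 with an estimated correlation) and early zygotic genes of 0.35 (camera adjusted p = 0.000474, and adjusted p = 0.821 with an estimated correlation). ERGO-1 targets had a median of 0.04 (camera adjusted p = 0.639).

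How much of the triple mutant change each further mutation returned towards N2 was measured in libraries not used to choose the genes. All 4 libraries of a quadruple mutant were set against 2 of the triple mutant, so differences between numbered libraries can enter the share. Without rde-1 the median share returned was 7.82% for genes higher in the triple mutant, with a range of 2.3% to 36.7% over the 6 divisions, and 7.81% for genes lower in it (-23.5% to 49.6%). Without rde-4 it was 19% for higher genes (3.37% to 74.5%) and 25.7% for lower genes (17.6% to 92.7%). The divisions chose between 68 and 2527 higher and between 5 and 2579 lower genes. The highest value of each range came from genes chosen in replicates 2 and 4. Ranges of the 2 strains overlap, and the difference between them was not tested. Across genes the change in the rde-4 quadruple against the triple mutant had a correlation of -0.604 with an axis of embryo age, the main axis of spread within the 4 genotypes other than N2 and the triple mutant, and that in the rde-1 quadruple mutant of -0.136, so a return through the mutation was not separated from a difference in embryo age.

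The rde-1 quadruple mutant against N2 showed what remained changed. F55C9.3 was at 221 ± 47.3 CPM (log2 fold change 5.16 ± 0.28, adjusted p = 1.1e-11), pals-28 at 5.56 ± 3.21 CPM (5.25 ± 0.76, adjusted p = 0.00014), gst-24 at 27.5 ± 18 CPM (4.13 ± 0.60, adjusted p = 0.00015) and hsp-70 at 31.2 ± 17.9 CPM (3.01 ± 0.52, adjusted p = 0.0011). ERGO-1 targets had 20 of 24 higher, or 22 higher and 1 lower when adjusted over the list alone (median 2.74, camera adjusted p = 1.63e-35, and adjusted p = 2.11e-05 with an estimated correlation). Pathogen response genes had 25 of 29 higher, or 28 when adjusted over the list alone (median 3.21, camera adjusted p = 2.89e-19, and adjusted p = 0.45 with an estimated correlation). Maternal transcripts had 15 of 34 lower, or 24 when adjusted over the list alone (median -0.92, camera adjusted p = 1.2e-08, and adjusted p = 0.452 with an estimated correlation). In all 1669 genes were called, 1141 higher and 528 lower, and limma on log2 FPKM gave 1256 higher and 149 lower. With stage markers as covariates 433 were called, 332 higher and 101 lower, and with only the 8 libraries of these strains in the fit 180. Of the 1141, 1088 were among the 1817 higher in the triple mutant, with N2 shared by both (127 for independent lists and a mean of 0 in 40 simulated draws of unchanged groups against the same N2 libraries). With N2 divided into 2 pairs of libraries, a median of 218 were shared of a median of 327.5 higher in the quadruple mutant. The count was 4577 without N2 replicate 1, 522 without N2 replicate 2, 2980 without N2 replicate 3, 555 without N2 replicate 4, and 821, 405 and 2899 without replicates 1, 3 and 4 of the quadruple mutant. F55C9.3, pals-28, gst-24 and hsp-70 stayed called in each of these omissions.

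In the rde-4 quadruple mutant against N2, F55C9.3 was at 257 ± 64.3 CPM (log2 fold change 5.38 ± 0.28, adjusted p = 7.9e-12), pals-28 at 3.46 ± 2.87 CPM (4.57 ± 0.76, adjusted p = 0.00073), gst-24 at 24.1 ± 14.9 CPM (3.93 ± 0.60, adjusted p = 0.00029) and hsp-70 at 27.4 ± 17.9 CPM (2.82 ± 0.52, adjusted p = 0.0023). ERGO-1 targets had 20 of 24 higher, or 22 when adjusted over the list alone (median 2.90, camera adjusted p = 5.8e-57, and adjusted p = 6.64e-07 with an estimated correlation). Pathogen response genes had 16 of 29 higher, 25 with library number as a block, or 26 higher and 1 lower when adjusted over the list alone (median 2.44, camera adjusted p = 4.01e-19, and adjusted p = 0.405 with an estimated correlation), and 9 without N2 replicate 2. Maternal transcripts had 0 of 34 called, or 10 lower with the block, and a median of -0.59 (camera adjusted p = 2.64e-06, and adjusted p = 0.623 with an estimated correlation, or 0.131 without N2 replicate 2). There were 452 calls, 430 higher and 22 lower, and with library number as a block 1793, 1302 higher and 491 lower. Of the 430, 426 were higher in the triple mutant too, again with N2 shared (47.7 for independent lists and a mean of 53.6 in the simulation, where 1 of 40 draws gave as many). With N2 divided, a median of 155.5 were shared of a median of 205. The count was 939 without N2 replicate 1, 282 without N2 replicate 2, 241 without N2 replicate 3, 288 without N2 replicate 4, and 261, 742 and 224 without replicates 1, 2 and 3 of the quadruple mutant. With only these 2 strains in the fit 82 genes were called, and pals-28 and hsp-70 had an adjusted p of 0.086 and 0.087.

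**Figure D4:**
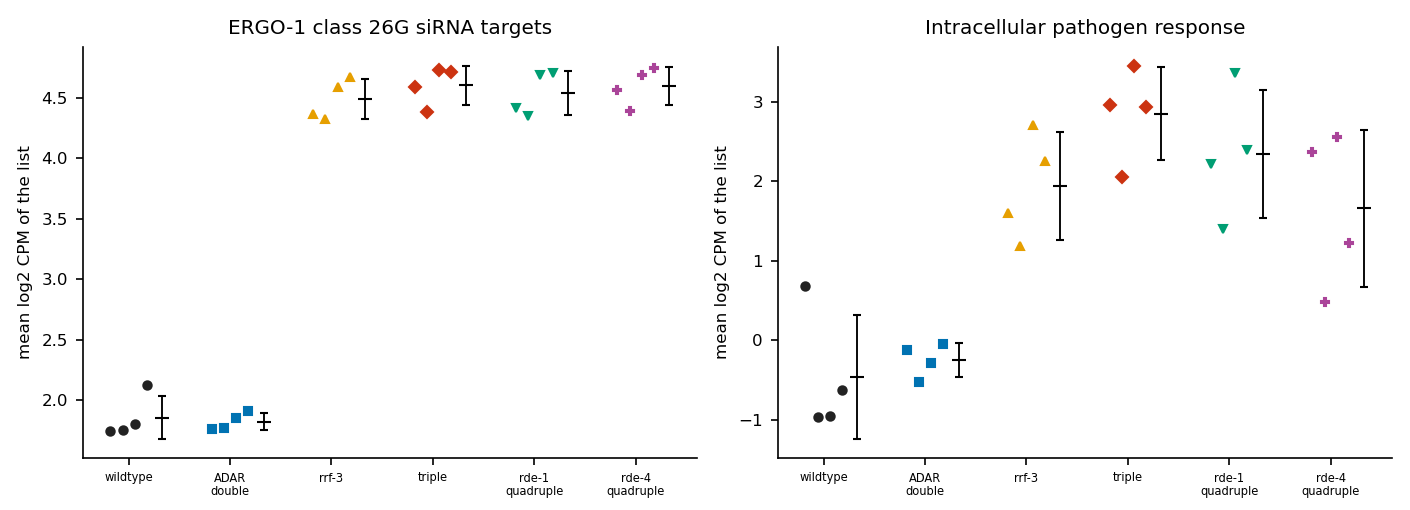
Mean log2 CPM of the ERGO-1 target list and of the intracellular pathogen response list in each library, by strain, with the mean ± SD of 4 libraries. The ERGO-1 targets were called in 20 or 21 of 24 members and the pathogen response genes in 16 to 26 of 29 members in the 4 strains without rrf-3 against N2.

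The 2 quadruple mutants differed in 3 genes, rde-1 (log2 fold change of the rde-1 over the rde-4 strain -3.40 ± 0.16, adjusted p = 3.6e-12), rde-4 (3.19 ± 0.23, adjusted p = 1.4e-08) and alg-1, at 403 ± 62 against 897 ± 71.7 CPM (-1.15 ± 0.16, adjusted p = 0.0021). Pathogen response genes had 0 of 29 called, also 0 when adjusted over the list alone, and a median of 0.64 (camera adjusted p = 4.05e-13, and adjusted p = 0.651 with an estimated correlation). Maternal transcripts had a median of -0.25 (camera adjusted p = 8.98e-08, and adjusted p = 0.731 with an estimated correlation) and early zygotic genes of -0.26 (camera adjusted p = 1.87e-06, and adjusted p = 0.731 with an estimated correlation). C-type lectins and detoxification enzymes passed only with library number as a block (camera adjusted p = 0.0619 and 0.0575 without it, 0.0459 in both with it, and 0.76 and 0.731 with an estimated correlation).

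Comparisons that share control libraries were set beside chance. The fold changes of the adr double mutant and of the rrf-3 mutant against N2 had a correlation across genes of 0.23. Unchanged groups against the same N2 libraries gave a mean of 0.474 and outer quantiles of -0.326 and 0.863, which are not the extremes of the draws. Their covariance was 0.062 against 0.0535 in the simulation. With N2 divided into 2 pairs of libraries the correlation was -0.108 (-0.428 to 0.286). They shared 2 higher calls (0.174 for independent lists) and 0 lower. Against the triple mutant, the fold changes of the quadruple mutants had a correlation of 0.625 (0.486 in the simulation, outer quantiles -0.0389 and 0.884), a covariance of 0.0473 (0.0568 in the simulation) and, with the triple mutant divided in the same way, a correlation of 0.153 (-0.124 to 0.333). They shared 0 calls. Genes are not independent replicates, and these values describe the overlap of the comparisons only.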

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

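Of the tests in this part, those with stage-marker covariates, the list tests without N2 replicate 2, those of reads of the pals family and of genes lower again, and the other divisions of the libraries for the 10 pairwise comparisons, with and without the mutated genes, were chosen only after the result was seen. Gene counts without each library had been chosen beforehand, and their use to weigh N2 replicate 2 as a cause came after.

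The first pattern is the large number of genes that differed between the triple mutant and N2, 3930. Along the main axis of spread within the 4 other genotypes (16 libraries, 52% of their within-group variance, oriented by late tissue markers), 94.4% of these genes moved in the direction of older embryos, 91.2% of the higher and 97% of the lower ones, where 51.8% of all tested genes have a positive loading. A difference in embryo age may therefore account for many calls, and whether it came from harvest or from the genotypes was not tested. Age as measured by the markers is not the whole cause, since 318 of 369 genes called with stage-marker covariates were called alike without them. N2 replicate 2 alone is argued against by 1501 genes called without it, 1104 higher and 397 lower (1817 and 2113 with it). That library may carry many of the lower calls.

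The second pattern is the higher level of intracellular pathogen response genes in strains that lack rrf-3. Embryo age is argued against as the whole cause in the rrf-3 mutant, where 14 members were called higher with stage-marker covariates against 18 without them (median log2 fold change 1.96 and 2.38), but it may carry part of the pattern, since the members called fell from 26 to 14 in the triple mutant (median 3.71 and 2.31), from 25 to 14 in the rde-1 quadruple mutant (3.21 and 2.17) and from 16 to 10 in the rde-4 quadruple mutant (2.44 and 1.84). N2 replicate 2 is argued against in the triple mutant, where 25 members were called without it against 26 with it, while in the rrf-3 mutant 9 were called without it and the median stayed at 2.24. Division of reads among pals copies is argued against as the whole cause by the 11 of 18 members outside that family called higher in the rrf-3 mutant, and for the pals genes themselves in the triple mutant by a summed level 3.56 times that of N2 (lowest 231 against highest 165 CPM), while in the rrf-3 mutant that level was 2.28 times that of N2 with libraries that overlap, which leaves it open for them there. A response of the embryos to loss of rrf-3 is a hypothesis only, since an infection of some cultures was not tested and stays possible, and the list did not pass with an estimated correlation (adjusted p = 0.336 in the rrf-3 mutant and 0.265 in the triple mutant).

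The third pattern is the higher level of alg-1 in the rde-4 quadruple mutant against the triple mutant. With stage-marker covariates the log2 fold change was 0.94 ± 0.16 (adjusted p = 0.046, edgeR) against 1.16 ± 0.16 without them, which argues against embryo age as the whole cause. The 20 nearest tested genes had a median log2 fold change of 0.14 (-0.41 to 0.57, 0 called by edgeR), which argues against a change of copy number that spans neighbouring genes and leaves a duplication of the gene alone open. Reads moved from the paralog alg-2 are argued against, because alg-2 was itself higher by 82.7 CPM (269 ± 50.8 and 351 ± 126 CPM) while alg-1 gained 495 CPM. Only 1 strain carried the rde-4 mutation, so loss of rde-4 and any other difference of that strain were not separated, and both remain candidate explanations.

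Other divisions of the 8 libraries of a comparison into 4 and 4, 35 in all with the real one, were run for each pairwise count. Where library numbers do not pair the samples, chance is argued against if the real division alone, 1 of 35, gave as many. This held for the rrf-3 mutant against N2 (485 genes, highest other 0), the triple mutant against N2 (3930, highest other 1145) and against the adr double mutant (1397, highest other 0). In the rde-4 quadruple against the triple mutant the real division alone gave 2 calls (highest other 1), but rde-4 itself is 1 of them, and without the mutated genes 2 of 35 gave as many as the real 1, so chance is not argued against there. Nor do the divisions argue against chance for the rde-1 quadruple mutant against N2, where 2 of 35 gave as many (1669, highest other 3628). The division with 3628 set N2 replicate 1 with replicates 1, 2 and 3 of the quadruple mutant against the rest. Of 40 simulated draws of unchanged groups 0 gave as many as the 1141 higher calls of that comparison (mean 0). The tests differ and chance stays open. In the 5 comparisons whose numbers pair the libraries, only the 8 divisions that part all 4 pairs keep the pairing, too few for a share below 0.05. There the real one gave 17 calls in adr against N2, 8 in the triple against the rrf-3 mutant, 1 in the rde-1 quadruple against the triple mutant, 452 in the rde-4 quadruple mutant against N2 and 3 between the quadruple mutants, and the highest of the other 7 gave 0 in each. The counts of 1 and 3 hold the mutated genes rde-1 and rde-4 themselves, and without them they are 0 and 1. Over all 35 divisions, which ignore the pairing, as many calls came from 2 (highest other 8897), 1 (0), 1 (0), 4 (9247) and 1 (0) of them, in the same order. The divisions with 8897 and 9247 calls set replicates 1 and 3 of both genotypes against replicates 2 and 4, which points to a structure of the samples other than genotype. With library number as a block the counts were 25 for adr and 1793 for the rde-4 quadruple mutant against N2. For adr against N2, 8 of the 11 lower genes were lower again in the triple against the rrf-3 mutant, in separate libraries. They include the mutated adr-1 and adr-2 and H15N14.4, numbered on the clone of adr-1, which do not bear on chance. For the 5 others as a set chance is argued against, as 34 divisions with group means removed and library numbers kept shared at most 0. For the interaction the real count is 0, so 100 of 100 drawn divisions give as many by construction (highest 5148) and decide nothing.

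For 8 gene lists the effect of ADAR loss differed between the strains with and without rrf-3 in the test of the interaction. Intracellular pathogen response genes had a median interaction of 0.75 on the log2 scale (camera adjusted p = 4.27e-07), the pals family of 0.76 (2.19e-06), histones of 0.36 (6.71e-07) and detoxification enzymes of 0.18 (0.00017). Maternal transcripts had a median of -0.14 (0.0207), muscle markers of -0.41 (1.36e-06), pharynx markers of -0.25 (0.0123) and epidermis markers of -0.15 (0.00256). With an estimated correlation the adjusted p was 0.902 for maternal transcripts and 0.881 for the other 7. Without N2 replicate 2, 14 lists passed. Of the 8, histones (adjusted p = 0.0646), muscle markers (0.271) and pharynx markers (0.99) then did not, and pathogen response genes (2.41e-07), the pals family (3.93e-09), detoxification enzymes (6.61e-06), maternal transcripts (6.34e-17) and epidermis markers (0.00666) did. With stage-marker covariates histones had an adjusted p of 0.0443, detoxification enzymes and the pals family of 0.437 and pathogen response genes of 0.628. The other 4 lists enter the covariates, so that test decides nothing for them.

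Single libraries stood far from the other 3 of their genotype in 11 of 234 groups of 4 values tested with Dixon's criterion, where about 1 in 20 such groups, 11.7 here, are found by chance. In adr replicate 4 the mean log2 CPM of secondary Argonautes was 3.946 (others 3.809 to 3.826) and that of heat shock and unfolded protein response genes 5.471 (5.987 to 6.068). In N2 replicate 4 ERGO-1 targets were at 2.122 (1.747 to 1.803), and in N2 replicate 1 pals-6 was at 1.33 CPM (0.314 to 0.45 CPM). In the triple mutant's replicate 3 early zygotic genes were at 3.208 (3.829 to 3.91). In replicate 4 of the rde-4 quadruple mutant ADAR-edited transcripts were at 5.59 (5.814 to 5.847) and F-box genes at 2.588 (2.507 to 2.516). In replicate 3 of the rde-1 quadruple mutant vitellogenins were at 1.008 (-0.05731 to 0.0426), maternal transcripts at 4.822 (5.394 to 5.429), A-to-I editing and dsRNA-binding protein genes at 5.572 (5.895 to 5.96) and rrf-3 at 35.2 CPM (47.6 to 50 CPM).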

How the results depend on the processing

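Of the tests in this part, those with stage-marker covariates, the list tests without N2 replicate 2, those with a FPKM pseudocount of 1 and the divided controls for calls shared with the triple mutant were chosen only after the results were seen. Of 205 calls of genes chosen by the rule for named genes, none turned sign in the settings run on them except 5 with stage-marker covariates. Counts that moved by more than 1.5 times follow, and where nothing else is said the cause was not tested. The Wald test of DESeq2 called 927 genes in rrf3 vs N2 (831 higher, 96 lower), 19 in the triple mutant vs rrf3, 2 in the rde-1 quadruple vs the triple mutant, 3381 and 792 in the rde-1 and rde-4 quadruple mutants vs N2, and 1 in the interaction. A fit to the 8 libraries compared called 2 in adr vs N2, 130 in rrf3 vs N2, 688 in the triple mutant vs N2 (651 higher, 37 lower), 3 in the triple mutant vs rrf3, 1 in the rde-4 quadruple vs the triple mutant, and 180 and 82 in the rde-1 and rde-4 quadruple mutants vs N2. In the triple vs the double mutant that fit called 1679 against 1397, so having fewer samples is not the whole account. The SD of the maternal mean was 0.623 in N2 and 0.185 to 0.328 in the other strains. The main fit takes 1 spread per gene for all strains, and the counts against N2 depend on that choice. An adjusted p below 0.01, a stricter threshold by construction, left 189 in rrf3 vs N2, 1006 in the triple mutant vs N2, 608 in the triple vs the double mutant, and 369 and 206 in the rde-1 and rde-4 quadruple mutants vs N2, and a change of at least 2-fold left 2029 in the triple mutant vs N2. Limma on log2 FPKM with a pseudocount of 1 called 307 in rrf3 vs N2, 1008 in the rde-1 and 263 in the rde-4 quadruple mutant vs N2. With a pseudocount of 0.1 it shifted the median log2 change of all genes by 0.22 in rrf3 vs N2, 0.27 in the triple mutant vs N2, 0.14 in the triple vs the double mutant, 0.2 and 0.16 in the rde-1 and rde-4 quadruple mutants vs N2, and -0.11 in the rde-4 quadruple vs the triple mutant, relative to TMM. Stage-marker covariates gave 34 in adr vs N2, 369 in the triple mutant vs N2, 14 in the triple mutant vs rrf3, 279 in the triple vs the double mutant, 433 in the rde-1 quadruple mutant vs N2 and 1 in the interaction. Of the 205 named calls 122 held with these covariates and 78 ended, and the 5 that turned sign, all in the triple mutant vs N2, were mut-16 (0.02 on the log2 scale), fem-3 (0.07), lin-13 (0.02), sdc-2 (0.06) and ergo-1 (0.03). Of the 297 list tests 150 passed with camera, 6 with an estimated correlation, 37 with fry and 69 with stage-marker covariates. Among the 150 in the same direction were all 6, 36 of the 37 and 45 of the 69. The correlation of the quadruple mutants' changes across genes was 0.153 with the triple mutant divided into 2 pairs against 0.625 with shared controls. Higher calls shared with the triple mutant vs N2 went from 1088 and 426 to medians of 218 and 155.5 for the rde-1 and rde-4 quadruple mutants with N2 divided into 2 pairs, which leaves fewer controls to each. The counts of calls with DESeq2 size factors in edgeR, without a filter and with a stricter filter stayed within 1.5 times of those reported. Of the named calls 204 of 205 held with size factors, 199 of 205 without a filter, 187 of 197 with the stricter filter, 205 of 205 with DESeq2 and 107 of 193 in the fit to the libraries compared. At 19200893 to 28938874 counts per library and 4 libraries per strain, 5.97% of the 1.5-fold changes simulated for adr vs N2 in independently drawn genes were recovered, so most changes of that size may be missed in that comparison.

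Library numbers as a block ended no call of a named gene (205 of 205 held). In the 5 comparisons whose numbers pair the libraries it added calls, with 25 in adr vs N2, and moved 3 counts by more than 1.5 times, to 16 in the triple mutant vs rrf3, 3 in the rde-1 quadruple vs the triple mutant and 1793 in the rde-4 quadruple mutant vs N2. In the other comparisons the correlations were not all over 0.1, so the numbers were not taken as a pairing. There the block gave 2288 calls in rrf3 vs N2 (pair correlations -0.34 to 0.2, with 1 of 8 libraries closest to its own number), 6595 in the triple mutant vs N2 (-0.05 to 0.38, 4 of 8), 3529 in the triple vs the double mutant (0.01 to 0.46, 5 of 8), 3 in the rde-4 quadruple vs the triple mutant (0.04 to 0.74, 6 of 8) and 5536 in the rde-1 quadruple mutant vs N2 (-0.04 to 0.48, 2 of 8).

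Leaving out each library in turn gave 12 to 17 calls in adr vs N2, 207 to 1084 in rrf3 vs N2, 1169 to 5468 in the triple mutant vs N2, 5 to 7 in the triple mutant vs rrf3, 708 to 1480 in the triple vs the double mutant, 1 to 2 in each quadruple vs the triple mutant, 405 to 4577 in the rde-1 and 224 to 939 in the rde-4 quadruple mutant vs N2, 3 in each case between the quadruple mutants and 0 in each case for the interaction. Of 1640 such values of named calls 1349 held, 291 ended and 0 turned sign.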

Other observations

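Of the tests in this part, all those of biotypes and families and of the 8 genes lower without ADARs were chosen only after the results were seen, and the genes named in the last paragraph were chosen after their values were seen.

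Transcripts that code for no protein were over-represented among the genes that rose without rrf-3. In the rrf-3 mutant against N2, 39 of 155 tested non-coding RNA genes were higher, where 11.8 would be for genes matched on expression (one-sided Fisher's exact test over 211 biotypes and families, adjusted p = 1.7e-23). Of 16 long intergenic RNA genes 7 were higher (0.79 matched, adjusted p = 8.1e-06) and of 564 pseudogenes 55 (30.7 matched, adjusted p = 2.7e-13). The 3 biotypes stood out again in the triple mutant, with 66 (39.6 matched, adjusted p = 1.8e-21), 11 (2.8 matched, adjusted p = 3.3e-06) and 137 (109 matched, adjusted p = 1.8e-17). In the rde-4 quadruple mutant against N2 the numbers were 46 (11.1 matched, adjusted p = 1.7e-33), 7 (0.707 matched, adjusted p = 4e-06) and 54 (27.7 matched, adjusted p = 1.4e-14). Called lower in the triple mutant were 1 non-coding RNA gene, 0 long intergenic RNA genes and 59 pseudogenes. The p-values take all tested genes as background, not genes matched on expression.

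Several protein families were over-represented among the higher genes as well. Only over-representation among higher genes was tested. In the rrf-3 mutant 16 of 129 fbxa F-box genes were higher and 0 lower (6.69 higher matched, adjusted p = 4.5e-05), and in the triple mutant 53 were higher and 5 lower (24.4 higher matched, adjusted p = 8.3e-17). The triple mutant also had 13 of 26 math genes higher and 1 lower (4.08 matched, adjusted p = 3.4e-05), 20 of 58 cytochrome P450 genes of the cyp family higher and 0 lower (9.41 matched, adjusted p = 6.3e-05), 7 of 12 pho genes, which encode acid phosphatases, higher and 0 lower (2.04 matched, adjusted p = 0.0026), 14 of 46 transthyretin-related ttr genes higher and 1 lower (4.54 matched, adjusted p = 0.0053) and 5 of 8 cnc genes, which encode caenacin peptides of the antimicrobial response, higher and 0 lower (0.997 matched, adjusted p = 0.0099). In the rde-1 quadruple mutant against N2, 38 of the fbxa genes were higher and 3 lower (15.7 matched, adjusted p = 4.7e-13), and 14 were higher and 0 lower in the rde-4 quadruple mutant (5.98 matched, adjusted p = 0.00032). Reads of fbxa, math and pals copies are hard to tell apart, so the numbers of members are uncertain.

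One hypothesis was that transcripts lower without ADARs are lost through RNAi and return when rde-1 or rde-4 is removed. It was put to the 8 genes lower in the adr double mutant against N2 other than adr-1, adr-2 and H15N14.4, which is numbered on the same clone as adr-1. In the triple against the rrf-3 mutant none had a positive log2 fold change, and the median was -1.18. The test fry of limma, adjusted over the 3 comparisons, gave an adjusted p = 3e-09 there. If the hypothesis held for the group, at least 7 would be positive in a quadruple against the triple mutant. Without rde-1 there were 4, with a median of 0.04, and without rde-4 there were 5, with a median of 0.11. Fry leaned higher in both, with an adjusted p = 0.0073 without rde-1 and adjusted p = 0.0073 without rde-4, but the prediction was not met for the group. The largest positive values were those of 3 genes. Y48G1BL.4 had log2 fold changes of 1.64 ± 0.32 without rde-1 and 1.48 ± 0.32 without rde-4 (edgeR adjusted p = 0.27 and 0.65), after -2.95 in the double mutant against N2. Y48G1BL.3 had 1.07 ± 0.25 and 1.12 ± 0.25 (adjusted p = 1 and 0.78) and C06A5.4 0.75 ± 0.24 and 0.79 ± 0.24 (adjusted p = 1 in both). None of these 3 was called by edgeR without a block. With library number as a block Y48G1BL.3 was called without rde-1 and without rde-4 (1.10 ± 0.18 and 1.13 ± 0.18, adjusted p = 0.035 and 0.016) and Y48G1BL.4 without rde-1 (1.67 ± 0.28, adjusted p = 0.043), and DESeq2 called Y48G1BL.4 in both (1.63 and 1.49, adjusted p = 0.00095 and 0.011). A return of Y48G1BL.3 and Y48G1BL.4 is therefore possible, and the call depends on the test. For Y48G1BL.3 the fall it would undo is itself uncertain, since its call in adr against N2 (-1.31 ± 0.25, adjusted p = 0.03) ended in 6 of the 8 omissions of a library (adjusted p between 0.053 and 0.29) and with only these 8 libraries in the fit (0.98). The other 5 had values between -0.33 and 0.13, alh-7 among them with -0.03 ± 0.22 and -0.08 ± 0.23.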
